A study of Homo sapiens with 6 samples.

How the data were processed

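RNA sequencing libraries from 6 samples of the human ocular melanoma cell line 92.1 were compared. The 3 control samples are labelled NC with a wild-type genotype, and the other 3 come from a derivative line with ALKBH3 knocked down, labelled shALKBH3, where the prefix is the usual one for short hairpin RNA. The labels do not say whether the NC cells carry a control hairpin. Total RNA was fragmented and random-primed, and the second cDNA strand was made with dUTP, per the labels' protocols. No label says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

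The authors deposited FPKM for each transcript, that is fragments scaled to transcript length and to the library's mapped fragments, per the file headers, with no read counts used here. The submitters' processing notes name the build hg19, HTSeq 0.6.0 and DESeq2, without saying what each was used for. The tool that estimated the transcript FPKM, the aligner and the annotation are not given in the sources used here. Each table lists the same 28900 transcripts. In every one of them the higher of the 2 group means is at least 0.5 FPKM, as a filter on low values would leave. No source used here states such a filter, and it does not give the level of any transcript outside the tables. Values reach down to 1e-06 FPKM, so they are model estimates and whole reads could not be recovered. Sequencing depth is therefore unknown, and no counting interval is given. Because the listed FPKM depend on how fragments were divided among transcripts of a gene, single transcripts are less certain than gene sums. Pearson correlations of log2 values between libraries ran from 0.821 to 0.850 for transcripts and from 0.947 to 0.972 for gene sums.

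Transcript identifiers were matched without their version to GENCODE release 29, which is built on GRCh38 and was used for gene names, chromosome, transcript length and GC content only. No coordinates are given because the submitters' notes name another build. Of the 28900 transcripts 28796 matched (99.6%) and 104 did not. The unmatched ones were left out. FPKM were summed over the listed transcripts of each gene, which gave 11387 genes. The 10475 genes with a mean of at least 1 FPKM over the 6 libraries were tested, and 912 below that level were not. Values were taken as log2(FPKM + 1), so every fold change is on that scale and understates the change of low genes. FPKM were not rescaled further.

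The comparison of shALKBH3 with NC used limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The second setting also takes its p-values from the 4 residual degrees of freedom, so they can be larger without any correlation. Lists with at least 5 tested members entered, and p-values were adjusted over those lists. The fry test was run beside it and asks whether a list's genes move one way on balance, without comparing them with other genes. Members of each list were also counted after adjustment over the list alone. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

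The contrast, the 33 gene lists, the thresholds, the rule for naming genes and part of the alternatives were fixed before the data were examined. The plan assumed read counts and a count model with a count-based filter. The deposited values are FPKM, so limma on log values took its place. The pseudocount, the FPKM filter, the summing to genes and the use of the deposited scale were chosen after the tables had been opened, when correlations between libraries at both levels and the values of ALKBH3, SP100 and PML had been seen. Counts from the same test on single transcripts are therefore reported beside the gene counts. Genes were named by rule: ALKBH3; the 12 largest rises and 12 largest falls among genes past the threshold whose libraries did not overlap between the groups; SP100, PML, DAXX and ATRX whatever their p; and the 4 members with the smallest adjusted p of each list described. Which lists are described member by member was settled after the values of the members of all 33 had been seen. They are the lists past the threshold, those with a member past it and the melanocyte list. Any other gene named was chosen after its values were seen. A gene that the rule took is not reported here.

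The test was checked on simulated data for 10475 genes with the spread of these libraries, 200 of them changed. It recovered 31.3% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 92.4% of those changed 4-fold. Among 128 simulated genes called, 6 were unchanged. Genes were drawn independently of each other, and changed genes only from those above a set level in NC. Correlation between genes, library trends with length and GC content, and changes in low genes were therefore not covered. The alternatives fixed in advance and run here were median-of-ratios scaling, no filter on low values, the replicate number as a block, leaving out each library, and the estimated correlation. Added after seeing the data were a pseudocount of 0.1, a minimum mean of 5 FPKM, quantile normalization, a correction for transcript length and GC content, array weights, no variance trend, the most abundant transcript of each gene, and the test of single transcripts.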

Results

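RNA from 92.1 cells, a human ocular melanoma line, was sequenced in 3 control libraries (NC) and 3 libraries with ALKBH3 knocked down (shALKBH3). ALKBH3 removes methyl groups from alkylated DNA and from 1-methyladenosine in RNA. The comparison asked how gene expression in these cells differs after the knockdown. Listed FPKM summed to 359151, 340950 and 361268 in NC replicates 1, 2 and 3, and to 333345, 326875 and 333987 in shALKBH3 replicates 1, 2 and 3. Every knockdown sum lay below every control sum, and values were not rescaled for this. Between 10328 and 10440 genes per library had at least 1 FPKM. Mitochondrially encoded transcripts made up 17.3%, 15.6% and 14.7% of the listed FPKM in NC replicates 1, 2 and 3, and 14.0%, 14.8% and 15.2% in shALKBH3 replicates 1, 2 and 3. Sequencing depth is unknown.

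ALKBH3 (ENSG00000166199, chromosome 11) was measured at 10.1 ± 0.787 FPKM in NC and 3.71 ± 0.487 FPKM in shALKBH3 (SD, 3 libraries each). The shALKBH3 mean was 63.3% lower, and all 3 knockdown libraries lay below all 3 controls. The log2 change was -1.24 (SE 0.118, limma adjusted p = 0.0079). Without NC replicate 1 the log2 change was -1.21 and the adjusted p 0.051, and with the most abundant transcript in place of the gene sum the adjusted p was 0.063. None of the other 17 tested genes in the list of AlkB-family demethylases and 1-methyladenosine writers and readers passed the test. Of the 18 members 3 had an unadjusted p under 0.05, ALKBH3 itself among them, all lower. HSD17B10, part of the mitochondrial tRNA-processing complex, had a log2 difference of -0.66 (adjusted p = 0.11). After adjustment over the list alone, 2 members were lower, ALKBH3 itself and HSD17B10. The list as a whole, which counts the knocked-down ALKBH3, did not pass (camera adjusted p = 0.12), and passed downward without shALKBH3 replicate 2 (0.036).

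**Figure D1:**
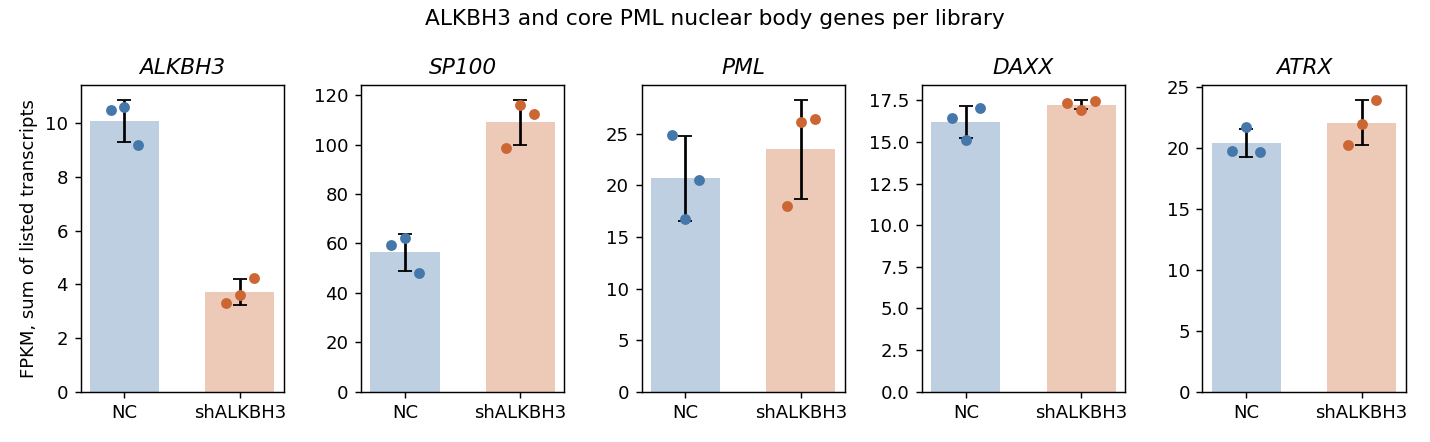
Gene-level FPKM (vertical axis, sum of listed transcripts) of ALKBH3, SP100, PML, DAXX and ATRX in the NC and shALKBH3 groups, where points are libraries, bars are means of 3 libraries and error bars are SD. ALKBH3 averaged 10.1 FPKM in NC and 3.71 FPKM in shALKBH3, SP100 averaged 56.4 and 109 FPKM, and the libraries of PML, DAXX and ATRX overlapped between the groups.

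Interferon-stimulated genes were the main group higher in the knockdown libraries. MX2, an antiviral dynamin-like GTPase, was at 6.76 ± 3.48 FPKM in NC and 38.1 ± 2.08 FPKM in shALKBH3 (SD, 3 libraries each), a log2 rise of 2.43. IFI27 rose by 2.24 on the log2 scale, the ISG15 protease gene USP18 by 1.99, IFI44L by 1.95 and IFIT2 by 1.93. BST2, which tethers budding virions, rose by 1.86, the RNA sensor gene OAS1 by 1.83, HERC5, which encodes the ligase for ISG15, by 1.78, and DDX58, which encodes the RNA sensor RIG-I, by 1.73. DDX60L rose by 1.74. The limma adjusted p-values of these 10 genes lay between 0.0011 (IFIT2) and 0.024 (MX2).

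Of the 36 tested members of the type I interferon list, 27 rose and 0 fell, and 33 were higher when adjusted over the list alone. All 36 had a positive log2 difference, with a median of 1.58, and the list passed camera (adjusted p = 1.5e-42) and passed with an estimated correlation (adjusted p = 0.024). Its smallest adjusted p-values belonged to IFIT3 (102 ± 4.03 FPKM in NC, 299 ± 3.42 in shALKBH3, SD, log2 1.54), IFIT2, IFI44 (log2 1.69) and IFIT1 (152 ± 8.26 against 435 ± 18.4 FPKM, log2 1.51). When single libraries were left out, between 19 and 25 of the 36 members passed, and MX2 missed the threshold without NC replicate 1 (adjusted p = 0.10) or shALKBH3 replicates 1, 2 and 3 (0.082, 0.11 and 0.11).

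**Figure D2:**
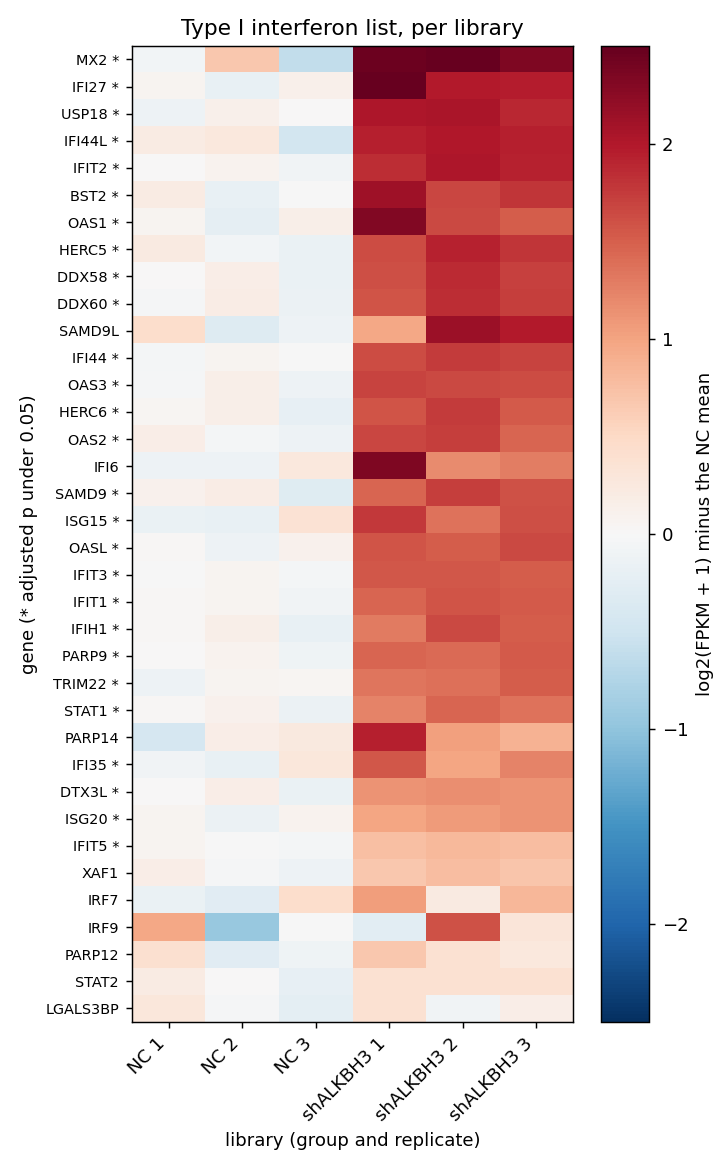
Each row is one of the 36 tested genes of the type I interferon list and each column one library, and colour gives log2(FPKM + 1) minus the mean of the 3 NC libraries. The 27 genes past the adjusted p threshold are starred, and the log2 differences between group means run up to 2.43 for MX2.

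Of 10475 genes, 134 were higher and 50 lower in shALKBH3 at a limma adjusted p under 0.05, and 73 of these changed at least 2-fold, 58 up and 15 down. In each of these 184 genes the 3 knockdown libraries lay on one side of the 3 controls. Among all tested genes 2609 (24.9%) were separated in that way, where 10% is the average over all splits into 3 and 3. Genes are not independent, so a single split can lie far from that average, and the share in the other splits was not computed. At an unadjusted p under 0.05 there were 941 genes higher and 854 lower. Leaving out any 1 library, and so fitting fewer samples, gave fewer genes in both directions. Without NC replicates 1, 2 and 3 in turn, 53, 87 and 68 genes were higher and 9, 22 and 15 lower. Without shALKBH3 replicates 1, 2 and 3, the counts were 59, 50 and 39 higher and 18, 12 and 9 lower. Genes changed at least 2-fold numbered 40 without shALKBH3 replicate 3. Of the 50 genes past the threshold that the naming rule took, ALKBH3 aside, 19, 29 and 27 passed without NC replicates 1, 2 and 3 and 22, 22 and 16 without shALKBH3 replicates 1, 2 and 3. Tested singly, 69 of 19765 transcripts were higher and 24 lower.

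Beyond the interferon genes, the largest rises were RUNX2 and TIGD1. RUNX2, a transcription factor of bone formation, was at 0.557 ± 0.665 FPKM in NC and 5.88 ± 1.26 in shALKBH3 (SD, 3 libraries each), a log2 rise of 2.21 (adjusted p = 0.032). TIGD1, a gene derived from a transposable element, was listed at 0 in NC replicates 1 and 2 and at 0.760 FPKM in NC replicate 3, and at 3.09, 3.76 and 3.42 FPKM in shALKBH3 replicates 1, 2 and 3 (adjusted p = 0.027).

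The largest fall was that of WDR75, a ribosome biogenesis factor, from 11.2 ± 6.78 to 0.716 ± 0.320 FPKM (SD, 3 libraries each), a log2 change of -2.70 (adjusted p = 0.034). Its adjusted p was 0.12, 0.089, 0.13 and 0.14 without NC replicate 1 or shALKBH3 replicates 1, 2 and 3. WDR75 has 1 listed transcript, so fragments moved to or from unlisted transcripts could not be checked. ELK3, an ETS-family transcription factor, fell from 57.9 ± 3.81 to 17.5 ± 1.13 FPKM (log2 -1.67, adjusted p = 0.0017). The immediate early gene EGR1 fell from 19.2 ± 0.465 to 7.93 ± 0.812 FPKM (log2 -1.18, adjusted p = 0.0044). The actin regulators FLNA and LIMK1 each had a log2 change of -1.25, with adjusted p-values of 0.047 and 0.040. The remaining largest falls were KRT81 (log2 -1.58), ANKRD28 (-1.56), PISD (-1.35), CSF2 (-1.29), SCG5 (-1.24) and CTU2 (-1.15), with adjusted p-values from 0.0040 (KRT81) to 0.048 (SCG5 and PISD). KRT81 has near-identical paralogs, so its value is uncertain.

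SP100, a structural component of PML nuclear bodies, rose from 56.4 ± 7.54 to 109 ± 9.29 FPKM (SD, 3 libraries each), a log2 change of 0.94 (SE 0.123, adjusted p = 0.026). Its relatives SP110 and SP140L rose by 1.37 and 1.26 on the log2 scale (adjusted p = 0.0040 each). PML itself had a log2 difference of 0.17 (adjusted p = 0.69), DAXX 0.09 (0.61) and ATRX 0.11 (0.58), and none of these passed. Of the 33 tested PML nuclear body genes 3 rose, 0 fell and 30 did not pass, with 3 higher when adjusted over the list alone. The 3 that rose were SP100, SP110 and SP140L, all on chromosome 2. Whether they rose apart from the interferon genes was not tested. The list passed camera upward (adjusted p = 0.0022) but not with an estimated correlation (adjusted p = 0.28), and its median log2 difference of 0.14 was 0.05 after the correction for length and GC content and 0.09 and 0.10 without shALKBH3 replicates 2 and 3. The SP100 call was lost without NC replicate 1 (adjusted p = 0.093), shALKBH3 replicate 1 (0.059), shALKBH3 replicate 2 (0.11) or shALKBH3 replicate 3 (0.12), and with the most abundant transcript in place of the gene sum (log2 0.54, adjusted p = 0.36). All 9 tested SP100 transcripts had positive log2 differences, but the smallest adjusted p among them was 0.11.

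In all, 15 of 29 tested lists passed camera, 7 upward and 8 downward, and the type I interferon list alone passed with an estimated correlation. Calls lost under that setting are not due to correlation alone, because it also uses fewer degrees of freedom. The unfolded protein response list, with an estimated correlation of -0.025, went from a camera adjusted p of 3.0e-04 to 0.11. The fry test gave an unadjusted p under 0.05 for 17 of the 29. Fold changes also followed transcript length across the 10475 genes (Spearman rho = 0.34) and GC content (rho = -0.31), where genes are not independent replicates. Against the mean of the 6 libraries, length rho was -0.18, 0.07 and -0.40 in NC replicates 1, 2 and 3 and 0.03, 0.31 and 0.27 in shALKBH3 replicates 1, 2 and 3. Median log2 differences ran from -0.15 in genes with transcripts of 207 to 1611 nucleotides to 0.11 in those of 5267 to 33679 nucleotides.

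**Figure D3:**
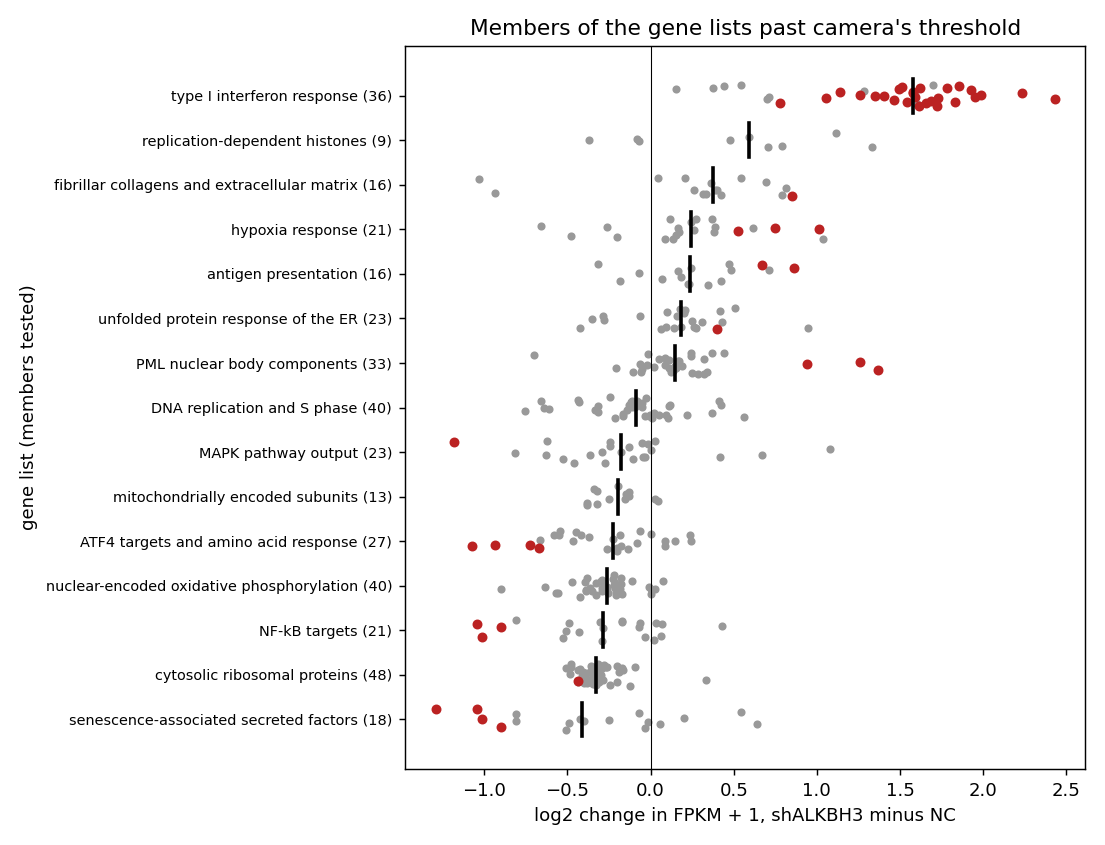
Log2 change in FPKM + 1, shALKBH3 minus NC (horizontal axis), of each tested member of the 15 gene lists past camera's threshold, with the number of tested members in brackets. Red points are genes with an adjusted p under 0.05, grey points are the others and black bars are list medians, from -0.41 for senescence-associated secreted factors to 1.58 for type I interferon response; the median of the mitochondrially encoded list is 0 under quantile normalization.

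Genes induced by low oxygen were higher as a list. ERO1A, an oxidase of the endoplasmic reticulum, rose from 33.3 ± 0.861 to 56.6 ± 1.22 FPKM (SD, 3 libraries each, log2 0.75, adjusted p = 0.0062). NDRG1 rose by 1.01 on the log2 scale as a gene sum, but its most abundant transcript alone had a log2 difference of -0.80. The collagen prolyl hydroxylase gene P4HA1 rose by 0.52, and P4HA2 had 0.62 without passing (adjusted p = 0.092). Of 21 tested hypoxia genes 3 rose and 0 fell, and 6 were higher when adjusted over the list alone (camera adjusted p = 4.1e-05, or adjusted p = 0.11 with an estimated correlation). The glycolysis genes HK2 (log2 0.54) and PFKFB3 (0.90) rose, as 2 of 25 tested members and 2 when adjusted over the list alone, while that list missed the threshold (camera adjusted p = 0.056) and passed after the correction for length and GC content (0.0044), without NC replicate 3 (0.011) and without shALKBH3 replicate 2 (0.00998).

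Antigen presentation genes also passed upward (camera adjusted p = 4.8e-04, or adjusted p = 0.36 with an estimated correlation). The peptide transporter gene TAP1 rose by 0.86 on the log2 scale and the aminopeptidase gene ERAP1 by 0.67, as 2 of 16 tested members, with 5 higher when adjusted over the list alone. PSMB9 had a log2 difference of 0.71 (adjusted p = 0.065). In the extracellular matrix list 1 of 16 tested genes rose, COL4A1 (85.8 ± 9.92 to 155 ± 4.49 FPKM, log2 0.85), and 9 were higher when adjusted over the list alone (camera adjusted p = 3.2e-06, or adjusted p = 0.26 with an estimated correlation). The median log2 difference of the matrix list was 0.38, and 0.28 after that correction. FBN1 had a log2 difference of 0.81 (adjusted p = 0.060) and POSTN 0.69 (0.088).

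The chaperone gene PDIA4 rose by 0.40, as 1 of 23 tested genes of the unfolded protein response, with 10 higher when adjusted over the list alone (camera adjusted p = 3.0e-04, or adjusted p = 0.11 with an estimated correlation). None of 9 tested replication-dependent histone genes passed singly in limma, with 6 higher at an unadjusted p under 0.05 and 6 when adjusted over the list alone (camera adjusted p = 0.0048, or adjusted p = 0.16 with an estimated correlation). HIST1H2BD had a log2 difference of 1.12 (adjusted p = 0.076), and histone genes of this class have near-identical copies. Without the filter on low values the histone list lost its call (adjusted p = 0.12).

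Senescence-associated secreted factors and NF-kB targets were lower as lists. The chemokine gene CXCL8 went from 236 ± 10.6 to 116 ± 3.76 FPKM (SD, 3 libraries each), a log2 change of -1.01 (adjusted p = 0.0030). CXCL2 and CXCL3 had log2 changes of -1.04 and -0.90 (adjusted p = 0.047 and 0.044), and the growth factor gene CSF2 -1.29 (adjusted p = 0.023). These 4 genes were the members that fell among 18 tested senescence-associated secreted factors, where 6 were lower and 3 higher when adjusted over the list alone (camera adjusted p = 0.0083, or adjusted p = 0.29 with an estimated correlation). The median of that list was -0.41, and -0.21 without NC replicate 1. With a minimum mean of 5 FPKM it was -0.07 and the call was lost (adjusted p = 0.20). CCL2, a member of both lists, had a log2 difference of -0.81 without passing (adjusted p = 0.065). The same 3 chemokine genes were those that fell among 21 tested NF-kB targets, with 5 lower when adjusted over the list alone (camera adjusted p = 3.5e-04, or adjusted p = 0.11 with an estimated correlation). EGR1 was the member that fell among 23 tested genes of MAPK pathway output, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0077, or adjusted p = 0.37 with an estimated correlation). The median of the MAPK list was -0.18, and -0.07 without NC replicate 3.

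Targets of the transcription factor ATF4 were lower as a list. PSAT1, a serine synthesis gene, went from 90.8 ± 2.00 to 56.5 ± 0.184 FPKM (SD, 3 libraries each), a log2 change of -0.67 (adjusted p = 0.0067). PHGDH, another serine synthesis gene, had a log2 change of -0.94, the asparagine synthetase gene ASNS of -0.73 and CHAC1, a glutathione-degrading enzyme gene, of -1.07 (adjusted p = 0.041, 0.041 and 0.040). They are 4 of 27 tested ATF4 targets, of which 11 were lower when adjusted over the list alone (camera adjusted p = 6.9e-06, or adjusted p = 0.11 with an estimated correlation).

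Cytosolic ribosomal protein genes were lower by small amounts. RPLP1 fell by 0.43 on the log2 scale (adjusted p = 0.037), the member that passed among 48. When adjusted over the list alone 34 were lower, and 47 of the 48 had negative differences, with a median of -0.33 (camera adjusted p = 2.9e-17, or adjusted p = 0.26 with an estimated correlation). Their typical transcript is short, with a median of 832 nucleotides, the trend with length was widest apart in NC replicate 3 and shALKBH3 replicate 2, and the list median was -0.21 after a correction for length and GC content and -0.16 under quantile normalization. Of 40 tested nuclear genes of oxidative phosphorylation 0 passed singly in limma and 0 when adjusted over the list alone, with 14 lower at an unadjusted p under 0.05 and a median of -0.26 (camera adjusted p = 8.3e-08, or adjusted p = 0.29 with an estimated correlation). CYC1 had a log2 difference of -0.56 (adjusted p = 0.088), and the median transcript of that list was 1147 nucleotides.

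None of the 13 mitochondrially encoded subunit genes passed singly in limma, with 6 lower at an unadjusted p under 0.05 and 5 when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 2.7e-04, or adjusted p = 0.37 with an estimated correlation), and it was -0.11 without NC replicate 1 and 0 under quantile normalization (adjusted p = 0.88). Quantile normalization gives equal ranks equal values, so genes that keep their rank are set to 0 there. The value of 0 therefore does not decide whether these genes fell. None of 40 tested DNA replication genes passed in limma, with 1 higher and 4 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone. That list passed camera downward (adjusted p = 0.047, or adjusted p = 0.26 with an estimated correlation), and its adjusted p was 0.11, 0.20 and 0.23 without NC replicate 1, NC replicate 2 and shALKBH3 replicate 1. It also missed the threshold with a minimum mean of 5 FPKM (0.11), with array weights (0.086) and with the most abundant transcript per gene (0.22).

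Further lists did not pass camera, and some held single genes past the limma threshold. CRIM1 rose by 0.52 on the log2 scale among 23 YAP and TAZ targets (camera adjusted p = 0.25), with 3 higher and 1 lower when adjusted over the list alone. SPARC, a matrix glycoprotein gene, went from 306 ± 10.6 to 219 ± 10.2 FPKM (SD, 3 libraries each), a log2 change of -0.48 among 23 genes of epithelial-mesenchymal transition (camera adjusted p = 0.81), with 2 higher and 2 lower when adjusted over the list alone. The 27 tested apoptosis regulators did not pass as a list (camera adjusted p = 0.80). CD68, a lysosomal protein gene used as a macrophage marker, rose from 16.3 ± 2.23 to 36.1 ± 2.04 FPKM as the one tested gene of the immune cell list, and 1.10 on the log2 scale (adjusted p = 0.010).

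Of the 29 melanocyte genes in the list, 7 were matched to a listed transcript, and no level is known for the others. Of those 7 genes, 6 were tested. None passed in limma, with 1 higher at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.70). MITF, the melanocyte lineage transcription factor, was at 6.91 ± 3.24 FPKM in NC and 11.8 ± 1.95 in shALKBH3 (SD, 3 libraries each, adjusted p = 0.31), and GPNMB had a log2 difference of 0.49 (adjusted p = 0.22). No gene passed in limma among the p53 targets (27 tested, camera adjusted p = 0.81), mitosis (42, 0.81), cholesterol synthesis (24, 0.088), lysosome and autophagy (31, 0.95), heat shock (20, 0.81), alkylation repair (22, 0.92), class 1 uveal melanoma (7, 0.80) or fibroblast (5, 0.92) lists. The cholesterol synthesis list passed downward without NC replicate 1 (adjusted p = 0.047) or shALKBH3 replicate 1 (0.028). At an unadjusted p under 0.05 these 8 lists held, in that order, 2, 1, 2, 4, 2, 1, 1 and 0 genes higher and 3, 2, 6, 0, 1, 2, 1 and 0 lower. When adjusted over the list alone, 1 cholesterol synthesis gene and 1 class 1 gene were higher, 1 gene of each of these lists was lower, and 1 heat shock gene was higher. The median, the mean and the camera direction differed in sign for the alkylation repair, mitosis, heat shock, lysosome, apoptosis and fibroblast lists. The class 2 uveal melanoma, epithelial and endothelial lists had 2, 3 and 2 tested members, of which 0 passed in limma and 0 had an unadjusted p under 0.05.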

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

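Quantile normalization, the correction for length and GC content, array weights, the fit without a variance trend, the most abundant transcript per gene, a pseudocount of 0.1 and a minimum mean of 5 FPKM were chosen after seeing the data. ALKBH3 stayed lower under every setting, from -1.3185 to -1.1734 on the log2 scale when single libraries were left out (adjusted p up to 0.051). Leaving out single libraries gave 39 to 87 genes higher, 9 to 22 lower, 40 to 82 changed at least 2-fold and 14 to 17 lists. Counts of higher and of lower genes fell in every such fit. The effect of having fewer samples was not separated from that of the library left out. Array weights gave 320 genes higher and 160 lower, the length and GC correction 81 lower, and the fit without a variance trend 27 lower. The most abundant transcript per gene gave 80 higher and 25 lower, with ALKBH3 at -1.2422 (adjusted p = 0.063). With an estimated correlation 1 list passed. The causes of these shifts were not tested. SP100 kept a positive log2 difference throughout, between 0.54 and 1.01. The count-model and voom fits and the read-based stricter filter fixed in advance were not run, because the deposited values are FPKM. FPKM with unknown depth set the limit for low genes.

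Deviations of same-numbered samples from their group means correlated at -0.088, 0.075 and -0.012 for pairs 1, 2 and 3 over gene values, and not every sample correlated best with its own number, so the numbers were not taken to pair them. With the replicate block the fit gave 17 genes higher, 3 lower and 20 changed at least 2-fold, with ALKBH3 at -1.2388 (adjusted p = 0.098) and 15 lists past the threshold. On single transcripts limma gave 93 changed without the block and 0 with it, where 1514 had an unadjusted p under 0.05, and 43 and 37 without shALKBH3 replicates 2 and 3. The block list for alkylation repair had a median of -0.0144 with the opposite camera direction.

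Some signs turned, and the cause was not tested. Quantile normalization put MT-ATP6 at 0.0139 and the median of the mitochondrially encoded list at 0. The length and GC correction put ATRX at -0.0889, RAB27A at -0.0076 and the mitosis list at -0.0513. The most abundant transcript put NDRG1 at -0.7983, RAB27A at -0.0889, NDUFS1 at 0.5134, XIAP at -0.3272, BMF at 0.3941 and the alkylation repair list at 0.0628. The class 1 uveal melanoma list turned in camera direction at a minimum of 5 FPKM, with a median of 0.1767. Among lists that did not pass, leaving out single libraries gave medians from -0.0346 to 0.0146 for alkylation repair, -0.0252 to 0.0705 for mitosis, -0.0109 to 0.2714 for class 1 uveal melanoma, -0.069 to 0.1291 for epithelial-mesenchymal transition, -0.0651 to 0.0014 for lysosome and autophagy and -0.0382 to 0.1008 for fibroblast markers, and camera's direction turned in at least 1 of these fits for each. The glycolysis list passed under median-of-ratios scaling (adjusted p = 0.048), quantile normalization (0.0021), the length and GC correction (0.0044) and array weights (0.035), and without NC replicate 3 (0.011) or shALKBH3 replicate 2 (0.00998). Cholesterol synthesis passed without NC replicate 1 (adjusted p = 0.047) or shALKBH3 replicate 1 (0.028) and at a minimum of 5 FPKM (0.037), and the AlkB list without shALKBH3 replicate 2 (0.036).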

Other observations

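The families and single genes of the first paragraphs and the test of transcript length were chosen after the results were seen. Of 33 tested TRIM genes 5 rose, TRIM14, TRIM21, TRIM25, TRIM38 and TRIM22, the last of which is in the interferon list (Fisher's exact test against all genes tested, two-sided, adjusted over 6 families, p = 1.7e-04). GBP1 (39.4 ± 2.85 to 86.6 ± 5.61 FPKM, SD, 3 libraries each) and GBP5 rose among 4 guanylate-binding genes (adjusted exact p = 0.0012), IFITM1 and IFITM2 among 3 (p = 7.2e-04) and APOL2 and APOL6 among 3 (p = 7.2e-04). Of 12 PARP genes 1 rose, PARP9, also in the interferon list (adjusted exact p = 0.14). The double-stranded RNA sensors EIF2AK2 and TLR3 rose by 1.01 and 0.98 on the log2 scale, and the RNA editing enzyme gene ADAR by 0.76. The interferon gene IFNE rose from 3.17 ± 0.171 to 5.99 ± 0.735 FPKM (log2 0.74, limma adjusted p = 0.044).

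Of 16 tested keratin and keratin-associated genes, 6 fell: KRT33B, KRT34, KRT80, KRT81, KRTAP2-3 and KRTAP2-4 (Fisher's exact test, adjusted p = 4.0e-10). KRTAP2-3 went from 197 ± 27.4 to 108 ± 6.76 FPKM and KRT80 from 80.1 ± 2.80 to 51.7 ± 2.43 (SD, 3 libraries each). Members of these families have near-identical copies, so they are not independent, and families picked for their changes give p-values that are too small. COL1A2 and COL3A1 were at 7.22 and 5.46 FPKM in NC replicate 1 and under 1 FPKM in the other 5 libraries.

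The rise of the interferon list was weighed against technical explanations. A difference in scale is argued against, since the list's median log2 change was at least 1.58 under median-of-ratios scaling and quantile normalization. Reassignment of fragments among listed transcripts is argued against for the 8 tested members with a single listed transcript, where the median was 1.212. With the most abundant transcript per gene, the median of the whole list was above that of these 8 members but below that of the gene sums. Reassignment toward the most abundant transcript could also raise the median taken with it. Fragments moved to or from unlisted transcripts could not be checked. Whether the rise may come from the hairpin itself and not from loss of ALKBH3 cannot be told apart. The labels distinguish 1 knockdown group, with no rescue. They also do not say whether the NC cells carry a control hairpin, so an effect of any hairpin stays open too. Loss of ALKBH3 stays a hypothesis.

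The lower ribosomal protein and oxidative phosphorylation lists had a joint median log2 change of -0.309. Genes matched on transcript length and mean level also had negative medians, with the middle 95% of 1000 draws from -0.23 to -0.14. The joint median lay below these draws, and a length trend could account for part of the shift. Whether it accounts for all of it is not settled. The matching took no account of GC content or of the correlation within the lists, estimated at 0.38 for ribosomal proteins and 0.28 for oxidative phosphorylation. A first match on coding length gave -0.22 to -0.12. The highest of the list medians under both rescalings was -0.162, for ribosomal proteins under quantile normalization, against -0.329 without rescaling. Median-of-ratios scaling, at -0.327, could hardly move that list, because the median over all genes was already -0.0096. These values argue against a scale difference common to all genes as the whole cause. A difference confined to abundant genes is not settled. The knockdown itself, and sample properties that moved with length in these libraries, stay open.

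A copy-number difference of whole chromosomes between the NC and shALKBH3 cells could move many genes. The chromosome median farthest from 0 was -0.115, for chromosome 19, inside the bound of 0.25 set for such a difference. Still, 8 of 23 chromosomes, 19 among them, had medians apart from random gene sets (permutation test with 10000 draws, adjusted p under the threshold), 3 higher and 5 lower. A copy change in part of the cells or of smaller segments stays open. So do the trends of fold change with transcript length and GC content, whose part in these medians was not tested.

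The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the largest result for each count. It gave 134 genes higher and 50 lower, where the highest other split gave 4 in a direction, 73 genes changed at least 2-fold against 6, 15 lists against 5 and 93 transcripts against 29.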
